A study of Mus musculus with 59 samples.

How the data were processed

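Total RNA sequencing of mouse embryonic stem cells (ESCs) was analysed. Per the labels, the lines were derived from BDF1 blastocysts and grown in serum medium with leukaemia inhibitory factor and the inhibitors CHIR99021 and PD0325901. Cells were either wild type (control) or knocked out for Zcchc8 (KO), and RNA was taken after 0, 4 and 8 h in Actinomycin D at 5 µg/ml, a drug that stops transcription. Each of the 6 groups held 2 replicates, so that 12 of the 59 samples of the series were used. The other 47 samples, from oocytes, embryos, RNA immunoprecipitation, open chromatin and steady-state ESC libraries, were not analysed here. Per the labels' protocols, ribosomal RNA was removed with the KAPA RiboErase kit and ERCC spike-in RNA was added. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

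The deposited values are a normalised signal: read counts per RefSeq transcript that the authors divided by 1 factor per library. Every value in a library was a whole multiple of the value of 1 read, to within 0.001 reads, for 100% of values, so whole reads could be recovered. The submitters' processing notes name TopHat2 2.1.1, HTSeq 0.6.0, DESeq2 and the build mm9, without settings. The strand setting of the counting and the rows behind the scaling factors are not given in the sources used here. The table as used here held 0 spike-in rows, so the values could not be rescaled to spike-ins. For that reason changes per hour are given on the scale of the authors' normalisation and no half-life is given. Rows for LINE1 or other repeats were not used here.

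The table had 33896 rows, of which 978 repeated another row and were dropped, leaving 32918 transcripts. Transcripts were summed by gene symbol to 23974 genes. Of the genes with 1 transcript, 34.3% had a mean value of at least 10 over the 12 libraries, against 8.47% of the 4888 genes with several transcripts. Many well known genes with several transcripts, such as Nanog, Gapdh and Rbm7, were at or near 0, so a low value of such a gene is not a measure of its RNA. Symbols were matched to a GRCm38 annotation only for chromosome and for overlap with coding exons on the opposite strand, with 23682 symbols (98.8%) matched and 3160 having such an overlap. Since the annotation is of another build than the authors used, no coordinates are given.

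Genes with a mean value of at least 10 over the 12 libraries were tested (6952 genes). The main test was limma 3.58.1 in R 4.3.3 on log2(value + 1), with the trend and robust options on, two-sided, with Benjamini-Hochberg adjustment over all genes tested and calls at an adjusted p below 0.05. A log2 change on this scale understates the change of low genes. KO was compared with control at 0, 4 and 8 h in 1 fit of 6 group means (6 residual degrees of freedom before moderation). Change per hour (slope) was fitted as a straight line per genotype over 0, 4 and 8 h (8 residual degrees of freedom). The difference of the slopes was tested as the genotype by time interaction. A line describes a decline that is curved, or that nears 0 early, only in part. Adjusted p-values without another tool's name are limma's.

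For gene lists fixed before the data were examined, camera was run with a preset correlation of 0.01 and again with an estimated correlation. With the estimated correlation no list was called in any comparison, and the lowest adjusted p was 0.242 (snoRNA and scaRNA genes at 8 h). That run used the deposited scale only, where offsets between libraries can raise the correlation of all genes. Its lack of a call therefore says little on any single list. It was planned for the 0 h comparison, the slope in control and the slope difference, and was added for the other comparisons after the data were seen. Of 32 lists, the 24 with at least 3 tested members entered the tests, adjusted over the lists of 1 comparison. Calls of list members were counted over all genes and adjusted over the list alone, and fry was run for change within a list.

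Genes were named by a rule fixed before the data were examined: Zcchc8 and its partners in the NEXT complex, then the 10 largest called changes in each direction (5 at 4 h and at 8 h) among genes with a mean of at least 100 in the higher group and, between genotypes, no overlap of replicates. For slopes the minimum applied at 0 h. Where no gene passed, the 3 with the smallest p in that direction were taken, and up to 4 members with the smallest p were taken from each list described. Genes chosen otherwise are said to have been chosen after their values were seen.

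Depth was low: 465324 to 1364523 reads were counted per library, and 1 read was worth 0.452 to 3.23 normalised units. The Zcchc8 value of each library is given with its reads as an example of what this depth allows. On simulated counts with 200 changed genes in 5 runs, the test recovered 91% of 4-fold and 29% of 2-fold changes at 0 h, with 13.2% of calls false over all tested genes and 4.4% among genes with a mean of at least 50. For the slope difference it recovered 56% of 4-fold and 6.6% of 2-fold differences over 8 h. The simulation placed changes only in genes above a minimum mean and gave each gene otherwise 1 mean over all groups. It took the spread after TMM scaling, so simulated replicates held no offset between libraries. Recovery in the real values may therefore be lower. Precision limits stated here cover counting error and the spread between these libraries only.

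Alternatives fixed before the data were examined were a pseudocount of 4, no filter, a mean of at least 50 and scaling by TMM factors. The replicate number as a block (for slopes also within genotype), the 4 compared libraries alone and leaving out each library were fixed as well. So were contrasts of 8 h or 4 h against 0 h in place of lines. The last were edgeR 4.0.16 on whole reads scaled as deposited and DESeq2 1.42.0 on whole reads with its own size factors. DESeq2 thus changed the scaling as well as the test. Tests of single transcripts, leaving out both libraries that stood apart, and leaving out chromosomes 6, 8 and 18 were added after the data were seen. TMM values express change relative to the bulk of genes and are given beside the main ones where they move a count or a direction. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.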

Results

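The RNA half-life experiment of the series asked how transcripts decay in mouse embryonic stem cells that lack Zcchc8, a zinc-knuckle protein that scaffolds the nuclear exosome targeting (NEXT) complex, which hands nuclear RNA to the exosome for degradation. Ribosomal RNA-depleted total RNA was sequenced from control and Zcchc8 KO cells after 0, 4 and 8 h in Actinomycin D, with 2 replicates in each of the 6 groups. Counted reads ranged from 465324 in control 0 h replicate 2 to 1364523 in KO 4 h replicate 1. All values below are the authors' normalised read counts, with SD over n = 2 libraries, and all changes are on the log2(value + 1) scale.

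Zcchc8 was lower in KO than in control before Actinomycin D. Its value was 59.3 (45 reads) and 77.5 (24 reads) in the control 0 h replicates, and 25.3 (15 reads) and 5.29 (3 reads) in the KO 0 h replicates. The log2 change was −2.42 (SE 0.681, adjusted p = 0.0332 by limma with Benjamini-Hochberg adjustment). At 4 h it was 32.7 (45 reads) and 24.7 (32 reads) in control against 21.3 (38 reads) and 13.6 (14 reads) in KO. At 8 h it was 7.57 (14 reads) and 11.3 (25 reads) against 9.56 (15 reads) and 3.78 (3 reads). Neither later difference was called, with log2 changes of −0.71 (adjusted p = 0.845) and −0.53 (adjusted p = 0.638). Skiv2l2 (Mtrex), the NEXT helicase, was not called at 0 h (log2 change 0.21, SE 0.417, adjusted p = 0.855), and Rbm7, the RNA-binding subunit, was listed at or near 0 and was not tested. The 0 h call of Zcchc8 was lost without KO 0 h replicate 2 (log2 change −1.39, adjusted p = 0.509) and with edgeR (−2.13, adjusted p = 0.0746). At an unaltered log2 change of −2.42 it was lost without either control 4 h replicate (adjusted p = 0.0563 and 0.0554), with no filter (0.0655) and with the 4 compared libraries alone (0.0877). Which part of the gene was deleted is not given in the sources used here, so the remaining reads check the labels only in part.

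The summed normalised value of the libraries fell with time in both genotypes. Control totals were 1162740 ± 481299 at 0 h, 709621 ± 119150 at 4 h and 402504 ± 59788 at 8 h, and KO totals were 1460509 ± 36483, 833247 ± 96717 and 683052 ± 105679. Rn45s, the ribosomal RNA precursor, held 15.3% ± 1.02 of the control total at 0 h and 0.306% ± 0.0110 at 4 h, and 14.6% ± 1.64 and 0.746% ± 0.0660 of the KO total. The median gene stood 0.44, 0.29 and 0.63 log2 units higher in KO at 0, 4 and 8 h on the deposited scale. It changed by −0.166 per hour in control and −0.143 per hour in KO. The values do not separate a shift of most RNAs from a shift by the library factors. Counts after TMM scaling, which centres the bulk of genes near 0, are therefore given beside the main ones. Control 0 h replicate 2 lay 0.86 log2 units above replicate 1 in the median gene. Without Rn45s its total (1283659) lay near the KO 0 h totals (1251479 and 1241274), while replicate 1 had 690451. The size of the KO shift at 0 h thus depends on the control replicate used. The KO 8 h replicates had the lowest correlation across genes (r = 0.901 over 2810 genes, against 0.922 to 0.969 in the other groups). No replicate pair was within sampling noise of being one library.

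**Figure D1:**
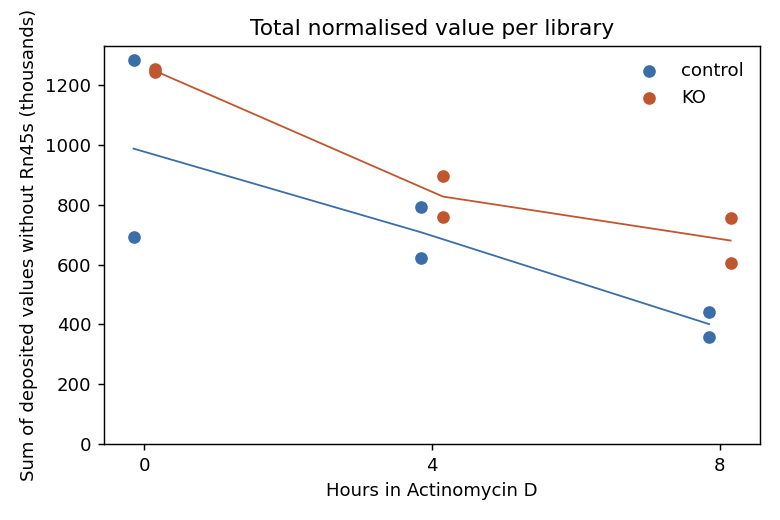
Sum of the authors' normalised values without Rn45s (in units of 1e3, vertical axis) against hours in Actinomycin D for each of the 12 libraries, with lines through the group means. The control 0 h replicates lie apart, at 690451 and 1283659, and the KO 0 h replicates lie together, at 1251479 and 1241274.

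In untreated cells (0 h), where the comparison asks how steady-state RNA differs, most called genes were higher in KO. Smpdl3b, a membrane-anchored phosphodiesterase, rose from 90.3 ± 55.0 to 862 ± 69.4 (n = 2 each; log2 change 3.38, SE 0.436, adjusted p = 6.61e-06). Zfp870, a zinc finger gene, rose from 21.9 ± 8.14 to 300.4 ± 41.4 (log2 change 3.76, SE 0.576, adjusted p = 0.000105). Hydin, a gene of motile cilia, rose from 5.57 ± 3.30 to 148 ± 24.4 (log2 change 4.59, SE 0.711, adjusted p = 0.000105). Cpne5 rose from 15.0 ± 2.97 to 133 ± 11.5 (log2 change 3.08, SE 0.555, adjusted p = 0.000505), and Zfp775 rose from 9.46 ± 0.334 to 138 ± 5.28 (log2 change 3.73, SE 0.723, adjusted p = 0.0013). The other genes with the largest called rises were Gpn3 (4.57), Nt5c2 (4.41), Hepacam (3.79), Rpl10l (3.18) and Fgf17 (3.05), all with adjusted p of at most 0.00505. Gpn3 and Nt5c2 overlap the coding genes Fam216a and Ina on the other strand, and Rpl10l is a near copy of Rpl10, so their reads are uncertain. The strand setting of the counting is not given. Reads from the opposite strand are therefore not excluded for the other genes named here and below either.

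In total 294 of 6952 genes were called higher and 5 lower at 0 h, and 94 higher and 27 lower after TMM scaling. Of the calls, 98.3% were higher on the deposited scale and 77.7% after TMM. Grin1os, annotated antisense to Grin1, was the one gene among the lower calls that passed the level rule (105 ± 70.5 in control and 14.7 ± 1.69 in KO, log2 change −2.59, adjusted p = 0.0013). The other lower calls were Zcchc8 and, named after their values were seen, Rhoa (−3.09, adjusted p = 0.013), Mut (−2.84, adjusted p = 0.0492, and 0.0553 after TMM) and Acaa2 (−1.82, adjusted p = 0.0438). Grin1os, Rhoa and Mut each overlap a coding gene on the other strand. Genes with such an overlap made up 11.9% of the higher calls (35 of 294) against 23.9% of tested genes, and 9.6% (9 of 94) after TMM. Fisher's exact test over genes, which are not independent, gave p = 1.82e-07 and 0.000561. The count of higher genes was 1132 without control 0 h replicate 2, 57 and 53 without KO 0 h replicate 1 or 2, and 187 and 190 without control 4 h replicate 1 or 2. The count of lower genes was 24 without control 0 h replicate 1, 10 and 8 without KO 8 h replicate 1 or 2, 1 without KO 0 h replicate 2, 2 without either control 4 h library and 3 without any 1 of the control 8 h and KO 4 h libraries. Hepacam, Rpl10l and Fgf17 lost the call without KO 0 h replicate 2 (adjusted p = 0.0525, 0.0903 and 0.0605), and Zfp775 without KO 0 h replicate 1 (0.0514). Rpl10l lost it also without control 0 h replicate 1, where its log2 change moved from 3.18 to 2.05. Gpn3 lost it without either KO 8 h library, at an unaltered log2 change of 4.57.

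**Figure D2:**
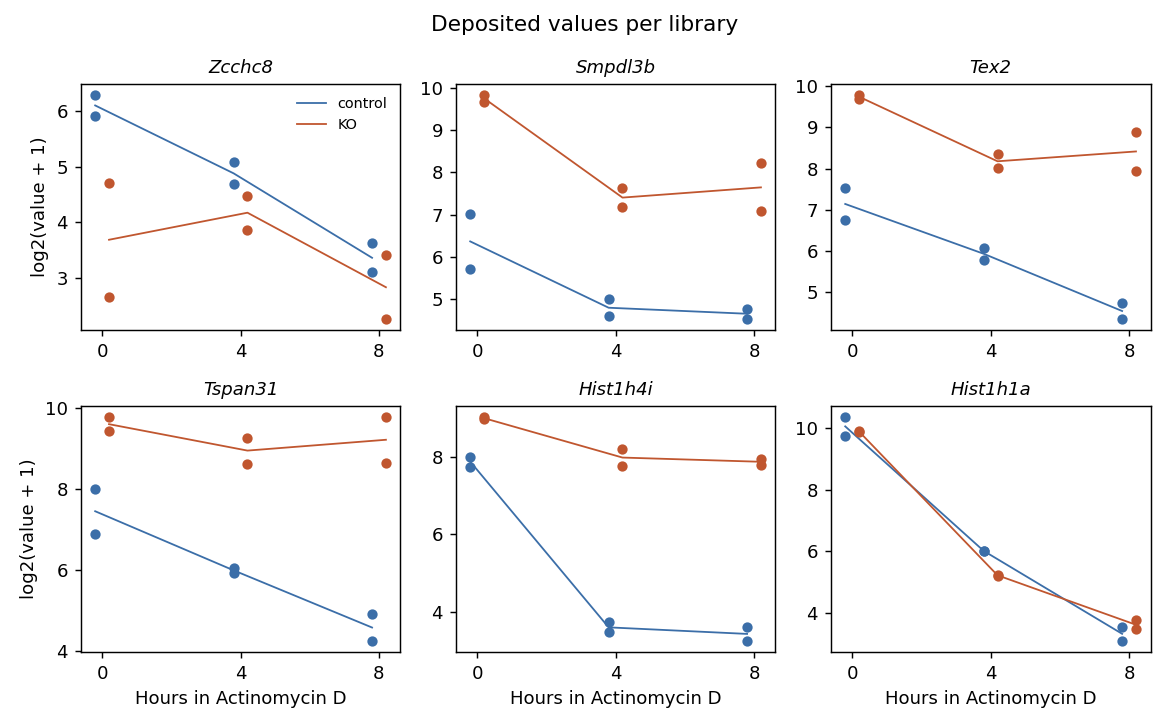
Deposited values on a log2(value + 1) axis against hours in Actinomycin D for 6 genes, 1 point per library and lines through the group means on that axis. Smpdl3b, Tex2 and Tspan31 lie higher in KO in both replicates at each time, Hist1h4i stays near 233 in KO at 8 h against 9.97 in control, and Hist1h1a falls in both genotypes.

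Among the gene lists, fibroblast marker genes were higher in KO at 0 h. Of 23 tested markers, 8 were called higher and 0 lower over all genes, and 21 higher and 0 lower adjusted over the list alone, with a median change of 1.26 (0.83 after TMM). After TMM 4 were called higher over all genes, and 17 higher and 1 lower adjusted over the list alone. Cdh11, a mesenchymal cadherin, was 45.1 ± 8.91 in control and 173 ± 62.6 in KO (log2 change 1.88, adjusted p = 0.00517). Thy1 was 74.5 ± 27.1 and 230 ± 23.3 (1.66, adjusted p = 0.0102). Acta2, a smooth muscle actin, was 394 ± 114 and 993 ± 122 (1.36, adjusted p = 0.0243), and Vim, an intermediate filament, 625 ± 204 and 1561 ± 258 (1.35, adjusted p = 0.0243). The labels name no feeder cells. The list stood apart from other genes with camera (adjusted p = 9.21e-06), but not with an estimated correlation (adjusted p = 0.811), and fry's mixed p was 0.000893.

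The only other list with a camera call at 0 h was that of snoRNA and scaRNA genes, with a median change of −0.66 over 8 members (adjusted p = 9.03e-05, and adjusted p = 0.811 with an estimated correlation). None of its members was called over all genes and 1 was lower adjusted over the list alone, while after TMM 1 was lower by either adjustment. Scarna13, a Cajal body RNA, had 52.6 ± 35.3 in control and 14.7 ± 1.69 in KO (log2 change −1.60, adjusted p = 0.0799), and was called after TMM (−1.98, adjusted p = 0.0215). In neuroectoderm, 2 of 7 markers were called higher and 4 adjusted over the list alone (0 and 2 after TMM). Over all genes these were Sox1 (log2 change 3.74, adjusted p = 0.0146) and Tubb3 (1.43, adjusted p = 0.0413), and after TMM neither was called (adjusted p = 0.0558 and 0.173). The list reached a camera adjusted p of 0.0948 (0.031 after TMM, and 0.811 with an estimated correlation). Of 8 nuclear long noncoding RNAs, Nespas (3.41, adjusted p = 0.00865) and Tsix (1.39, adjusted p = 0.0385) were called higher. After TMM Nespas was called (adjusted p = 0.0371) and Tsix was not (0.0767), with 2 members higher and 1 lower adjusted over the list alone. Both are antisense transcripts, whose reads cannot be told from those of their partners without strand. None of 51 replication-dependent histone genes and none of 21 naive pluripotency genes was called, over all genes or adjusted over the list alone, except 1 naive pluripotency gene that was lower over the list alone after TMM. Their medians were 0.29 and 0.22 on the deposited scale and lay below 0 after TMM, at −0.14 and −0.20. Of 66 ribosomal protein genes, Rpl10l alone was called, over all genes and adjusted over the list alone, and the list median was 0.25 (−0.18 after TMM; camera adjusted p = 0.225). After TMM 1 member was also called lower, 2 over the list alone, and camera set the list lower than other genes (adjusted p = 0.00597, not run with an estimated correlation). Of 9 nuclear exosome genes none was called over all genes and 1 was higher adjusted over the list alone, where Exosc4 had a change of 1.63 (adjusted p = 0.0577 over all genes), and after TMM none was called by either adjustment.

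After 4 h in Actinomycin D, Hist1h4i, a replication-dependent histone gene, was 11.3 ± 1.53 in control and 253 ± 51.4 in KO (log2 change 4.36, SE 0.399, adjusted p = 3.1e-10). Tspan31, a tetraspanin gene that overlaps Cdk4 on the other strand, was 62.3 ± 3.69 and 503 ± 156 (log2 change 2.96, SE 0.42, adjusted p = 3.66e-05). Ap1b1, an adaptor complex subunit, was 16.8 ± 0.879 and 131 ± 23.3 (log2 change 2.88, SE 0.485, adjusted p = 0.000343). Smpdl3b (2.61, adjusted p = 0.00033) and the clone gene 4930470H14Rik (2.42, adjusted p = 0.000212) were also higher. Of the genes named at 0 h, Zfp775 (4.60, adjusted p = 0.000183), Hepacam (3.85, adjusted p = 0.00328) and Cpne5 (2.87, adjusted p = 0.00279) were called. Hydin (2.54), Nt5c2 (2.57), Fgf17 (2.27), Zfp870 (2.12), Rpl10l (2.06), Gpn3 (0.76) and Grin1os (−1.47) were not, with adjusted p from 0.073 to 0.884. In all, 52 genes were called higher and 0 lower, with 58 lower at an unadjusted p below 0.05. EdgeR on the deposited scale called 2 lower and DESeq2, with its own size factors, 49. TMM scaling gave 46 higher and 17 lower, which took the higher share of calls from 100% to 73%. Genes with a coding overlap on the other strand made up 17.3% of the higher calls (9 of 52; Fisher's exact test p = 0.328) and 15.2% after TMM (7 of 46; p = 0.222). Of 23 fibroblast markers none was called over all genes and 15 were higher adjusted over the list alone (2 and 16 after TMM), with a median of 0.93 (0.63 after TMM). Camera, added after the data were seen, gave the list an adjusted p of 1.68e-07, and adjusted p = 0.959 with an estimated correlation. The 51 replication-dependent histone genes lay lower than other genes, with a median of −0.11 but a mean of 0.08 (median −0.41 after TMM; camera adjusted p = 0.025, and adjusted p = 0.959 with an estimated correlation). Of them 1 was called higher and 0 lower, over all genes and adjusted over the list alone, and after TMM 1 higher and 1 lower, with 5 lower adjusted over the list alone. The 8 snoRNA and scaRNA genes had a median of 0.45 (0.17 after TMM) with 0 called (1 lower over the list alone after TMM) and a camera adjusted p of 0.918. The lower genes with the smallest p were Sdr39u1 (−1.49, adjusted p = 0.0786), A930012L18Rik (−1.60, adjusted p = 0.073) and Lrrtm2 (−2.36, adjusted p = 0.0846), none of them called on the deposited scale. After TMM Sdr39u1 (−1.79, adjusted p = 0.00105) and A930012L18Rik (−1.90, adjusted p = 0.00971) were called lower, as was Grin1os (−1.77, adjusted p = 0.0321). The higher count was 180 and 187 without control 0 h replicate 1 or 2, 13 and 30 without control 4 h replicate 1 or 2, and 15 and 12 without KO 4 h replicate 1 or 2. The lower count was 8 and 7 without control 0 h replicate 1 or 2 and 3 without either KO 8 h library. Without control 4 h replicate 1, Smpdl3b (adjusted p = 0.0552) and 4930470H14Rik (adjusted p = 0.0511) lost the call.

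After 8 h, Tspan31 was 23.4 ± 7.83 in control and 637 ± 337 in KO (log2 change 4.64, SE 0.42, adjusted p = 1.18e-10), and Hist1h4i 9.97 ± 1.96 and 233 ± 18.1 (4.42, SE 0.399, adjusted p = 1.18e-10). Mogs, a glucosidase of glycoprotein processing, was 13.2 ± 9.47 and 217 ± 84.6 (4.07, SE 0.491, adjusted p = 2.32e-07). Tex2 was 22.6 ± 4.45 and 359 ± 164 (3.87, SE 0.402, adjusted p = 5.88e-09), and 4930470H14Rik 1507 ± 267 and 17470 ± 10210 (3.41, SE 0.394, adjusted p = 8.91e-08). Of the genes named at 0 h, Zfp775 (5.29), Hydin (4.26), Nt5c2 (3.24), Fgf17 (3.06), Hepacam (3.06), Smpdl3b (2.99), Cpne5 (2.65), Rpl10l (2.31) and Zfp870 (1.99) were called. After TMM Hepacam (adjusted p = 0.0905), Rpl10l (0.215) and Zfp870 (0.253) were not. Gpn3 (1.13, adjusted p = 0.427) and Grin1os (0.20, adjusted p = 0.818) were not. Altogether 339 genes were called higher and 1 lower, against 100 and 19 after TMM, a higher share of 99.7% and 84%. The lower call was Khnyn (−2.08, SE 0.637, adjusted p = 0.0468), which lay below the level of 100 and overlaps Sdr39u1. Its change was −1.16 without KO 8 h replicate 2, and −1.75 and −2.40 without control 8 h replicate 1 or 2. Hist1h4f (−2.16, adjusted p = 0.0676) and Hist1h2bm (−1.35, adjusted p = 0.0906) were not called, but after TMM Hist1h2bm was (−2.04, adjusted p = 0.0221). Genes with a coding overlap on the other strand made up 32.7% of the higher calls (111 of 339; Fisher's exact test p = 0.000103) and 20% after TMM (20 of 100; p = 0.409). Fibroblast markers had a median of 0.75 at 8 h (0.09 after TMM) with 0 of 23 called, at a camera adjusted p of 0.556. The higher count was 46 without KO 8 h replicate 2, 743 without KO 8 h replicate 1, 77 and 212 without control 8 h replicate 1 or 2, and 1011 and 1001 without control 0 h replicate 1 or 2. The lower count was 33 without KO 8 h replicate 1, 9 and 7 without control 0 h replicate 1 or 2, and 0 without any 1 of the other 9 libraries, where Khnyn lost its call (adjusted p from 0.0506 to 0.534).

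The higher calls at different times shared more genes than independent lists of their sizes would. The 0 and 4 h calls shared 29 genes (2.2 expected), the 0 and 8 h calls 64 (14.3 expected) and the 4 and 8 h calls 40 (2.54 expected). After TMM they shared 21, 28 and 26 (0.62, 1.35 and 0.66 expected). The comparisons use different libraries but the same cell lines and one estimate of the spread, so the excess is not a test of a shared effect. At all 3 times 25 genes were called higher on the deposited scale and 15 after TMM, the latter including Smpdl3b, Tex2, Tspan31, Mogs, Ap1b1, Cpne5, Zfp775 and Lefty2, a Nodal inhibitor. By chromosome, the median change after TMM was −0.39, −0.37 and −0.41 at 0, 4 and 8 h over 202 genes of chromosome 18. It was 0.31, 0.26 and 0.24 over 336 genes of chromosome 6, and 0.19, 0.17 and 0.20 over 421 genes of chromosome 8. Chromosome 18 held 7 of 27, 5 of 17 and 6 of 19 lower calls after TMM (Fisher's exact test p = 8.54e-06, 9.17e-05 and 1.11e-05 over genes). Among them were Impa2 and Lmnb1, the only genes called lower at all 3 times after TMM, named after their values were seen.

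**Figure D3:**
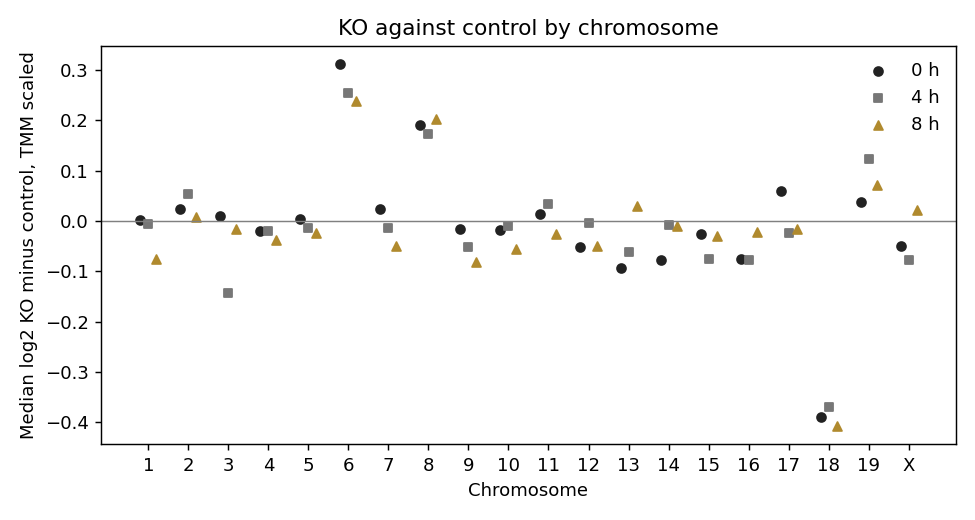
Median log2 KO minus control after TMM scaling (vertical axis) for the tested genes of each chromosome (horizontal axis), with 1 symbol per time in Actinomycin D. Chromosome 18 lies near −0.4 and chromosomes 6 and 8 lie above 0.17 at each time, while the other chromosomes lie between −0.144 and 0.124.

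In control cells, histone genes made up most of the largest declines after transcription was stopped. Hist1h1a, a linker histone, fell by 0.839 log2 units per hour (SE 0.066, adjusted p = 4.37e-10), from 1079 ± 320 at 0 h to 9.20 ± 2.32 at 8 h, or 0.853% of the 0 h level. Hist1h2bn fell by 0.896 per hour (SE 0.078, adjusted p = 3.51e-09). Rn45s fell by 0.892 per hour (SE 0.179, adjusted p = 0.00384) to 0.796%, and Nlrp12, an inflammasome-related gene, by 0.921 per hour (SE 0.175, adjusted p = 0.00157) to 0.344%. The other largest declines were of Hist1h3b (−0.906), Hist1h3h (−0.901), Hist2h4 (−0.875), Hist4h4 (−0.852), Hist1h2ac (−0.840) and Hist1h1d (−0.831). Reads of histone genes can be shared between near-identical copies. Hist1h3b lost the call without both libraries that stood apart (−0.810, adjusted p = 0.0615). Zcchc8 fell by 0.343 per hour (SE 0.087, adjusted p = 0.00202), a call that TMM scaling ended (−0.177, adjusted p = 0.155), and Skiv2l2 by 0.341 (SE 0.051, adjusted p = 6.83e-06). In all, 3620 genes were called lower and 31 higher with time, against 614 and 572 after TMM, a higher share of 0.8% and 48.2%. The higher genes with the smallest p, all below a value of 100, were Qsox1 (0.465 per hour, adjusted p = 0.000729), Efemp1 (0.284, adjusted p = 0.000977) and Lgals3bp (0.351, adjusted p = 0.00395). Lgals3bp was not called without control 0 h replicate 2 (0.143, adjusted p = 0.18). The lower count was 1849 without control 0 h replicate 2 and 1998 without control 8 h replicate 1, and the higher count 52 without control 0 h replicate 1 and 16 and 13 without control 8 h replicate 1 or 2.

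As groups, 50 of 51 replication-dependent histone genes were called lower with time in control, and 51 adjusted over the list alone. Their median was −0.692 per hour against −0.166 for all genes (camera adjusted p = 1.62e-23, and adjusted p = 0.668 with an estimated correlation). Of 21 naive pluripotency genes 18 fell, over all genes and adjusted over the list alone (median −0.302; camera adjusted p = 0.00773, and adjusted p = 0.668 with an estimated correlation). After TMM 7 were lower and 2 higher, and 10 lower and 3 higher adjusted over the list alone, with a median of −0.129. They included Klf2 (−0.618), Zfp42 (−0.423), Fbxo15 (−0.398) and Sall4 (−0.302). Of 23 immediate early and labile genes 19 fell, 20 adjusted over the list alone (median −0.342; camera adjusted p = 0.02, and adjusted p = 0.668 with an estimated correlation), among them Mycn (−0.552), Klf4 (−0.541) and Spry2 (−0.527). After TMM 6 were lower and 0 higher, and 8 lower adjusted over the list alone, with a median of −0.211. Klf2 and Klf4 belong to both lists. The lists that stood above the bulk of genes were fibroblast markers (median 0.017 per hour, 2 of 23 lower; camera adjusted p = 2.31e-09) and nuclear genes of the respiratory chain (−0.041, 3 of 20 lower; 0.000796). So did snoRNA and scaRNA genes (−0.058, 1 of 8 lower; 0.00534) and ribosomal protein genes (−0.083, 11 of 66 lower; 0.0453). Adjusted over the list alone, 0, 0, 0 and 3 of these members were lower, and with an estimated correlation the adjusted p was 0.668, 0.668, 0.668 and 0.822. The higher medians of these 4 lists are relative to other genes, and after TMM scaling they lay between 0.093 and 0.193 per hour. None of their members was then lower over all genes, and 19 fibroblast markers, 10 respiratory chain genes, 2 snoRNA and scaRNA genes and 30 ribosomal protein genes were higher. Adjusted over the list alone, 19, 11, 3 and 50 were higher after TMM, and 1 fibroblast marker was lower. The camera call of the snoRNA and scaRNA list was lost after TMM (adjusted p = 0.152).

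**Figure D4:**
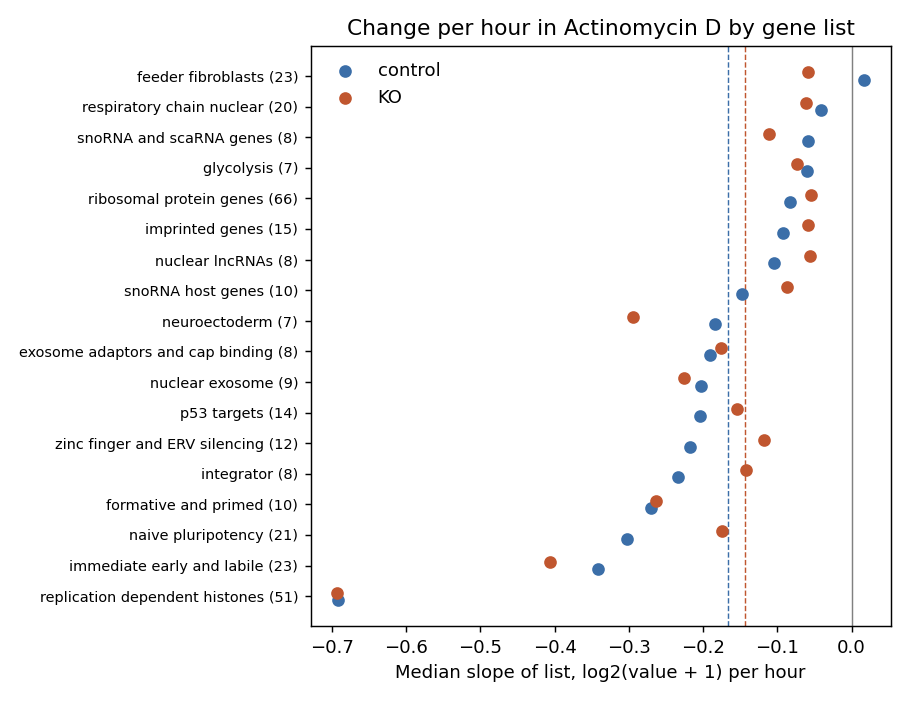
Median slope in log2(value + 1) per hour (horizontal axis) for each gene list with at least 7 tested members (vertical axis, members in brackets), in control and KO. Dashed lines mark the medians of all genes, −0.166 in control and −0.143 in KO, and histone genes lie at −0.692 and −0.693.

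In KO cells, histone genes made up most of the largest declines. Hist1h2bm fell by 0.960 log2 units per hour (SE 0.072, adjusted p = 4.5e-10), and Hist1h3e, which fell by 0.811 (SE 0.062, adjusted p = 2.02e-10), had 1147 ± 248 at 0 h and 11.7 ± 2.34 at 8 h. The other largest declines were of Hist1h4f (−0.928), Hist1h3h (−0.912), Hist1h2ac (−0.908), Hist1h1b (−0.870), Ypel4 (−0.855), Hist1h2ae (−0.835), Hist1h2ba (−0.815) and Hist2h3b (−0.801). Hist1h2ba was not called without KO 0 h replicate 2 (−0.552, adjusted p = 0.133). Of 51 replication-dependent histone genes 50 fell, over all genes and adjusted over the list alone. Their median was −0.693 per hour (camera, added after the data were seen, adjusted p = 7.48e-37, and adjusted p = 0.589 with an estimated correlation). Zcchc8 had a slope of −0.107 (adjusted p = 0.307) and Skiv2l2 of −0.231 (SE 0.051, adjusted p = 0.00124; −0.085, adjusted p = 0.183 after TMM). In all, 2596 genes were called lower and 2 higher, against 263 and 196 after TMM, a higher share of 0.1% and 42.7%. The 2 higher calls, both below a value of 100 at 0 h and overlapping a coding gene on the other strand, were Rhoa (0.349, adjusted p = 0.0104) and Grin1os (0.195, adjusted p = 0.0144). A430033K04Rik (0.218, adjusted p = 0.053) came next without a call, and was called after TMM (0.357, adjusted p = 0.0136). Rhoa was not called without KO 0 h replicate 2 (0.136, adjusted p = 0.276), nor Grin1os without KO 0 h replicate 1 (adjusted p = 0.0729) or KO 8 h replicate 1 or 2 (0.0516 and 0.0574). The lower count was 963 and 1117 without KO 0 h replicate 1 or 2 and 1530 without KO 8 h replicate 1, and the higher count 5 and 7 without control 0 h replicate 1 or 2 and 1 without KO 8 h replicate 2.

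Whether decay itself differed between genotypes was tested by the difference of the straight-line slopes, and limma called 0 of 6952 genes. A line puts the curvature of a decline into the residual spread, which weakens this test. Hist1h4i in control, for example, was 234 at 0 h, 11.3 at 4 h and 9.97 at 8 h. The contrast of 8 h against 0 h called 1 gene higher, Hist1h4i. The 0 calls are therefore not evidence of equal decay. At an unadjusted p below 0.05 there were 350 genes (488 after TMM, also with 0 calls). EdgeR on the deposited scale called 0, and DESeq2, with its own size factors, called 4 higher and 0 lower. The genes with the smallest p were B3galt2 (0.542 per hour higher in KO, SE 0.122, adjusted p = 0.653), Tspan31 (0.311, SE 0.075, adjusted p = 0.653) and Grin1os (0.348, SE 0.087, adjusted p = 0.672). In the other direction they were Qsox1 (−0.561, SE 0.149, adjusted p = 0.8), Flt1 (−0.411, adjusted p = 0.905) and Orai2 (−0.497, adjusted p = 0.905). Zcchc8 had a difference of 0.236 (adjusted p = 0.951) and Skiv2l2 of 0.111 (adjusted p = 0.951). B3galt2, Tspan31, Grin1os and Skiv2l2 overlap a coding gene on the other strand. Of the lists, fibroblast markers alone had a camera call, with a median of −0.064 per hour (adjusted p = 0.0033, and adjusted p = 0.911 with an estimated correlation). None of its 23 members was called, over all genes or adjusted over the list alone. Histone genes had a median difference of 0.012 per hour with 0 of 51 called. Naive pluripotency genes had a median of 0.046 with 0 of 21 called and 2 higher adjusted over the list alone (0 after TMM). Of these genes Dppa3 (0.479, adjusted p = 0.8) and Fbxo15 (0.352, adjusted p = 0.905) had the smallest p. Across genes, which are not independent replicates, the slopes of control and KO had a Pearson r of 0.614 over 6952 genes and 0.833 over the 2810 genes with a mean of at least 50. On simulated counts, which held no offset between replicate libraries, the test found 56% of 4-fold and 6.6% of 2-fold differences over 8 h. Smaller differences were thus mostly not detectable, and detection in the real values may be lower still. Without control 0 h replicate 1, 5 genes were called higher, and without KO 8 h replicate 1, 1 gene was called lower.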

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

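The tests of counting without strand, of a larger share of fibroblasts and of the library scaling were chosen only after the result was seen.

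Hist1h4i, a replication-dependent histone gene, differed between genotypes in its change over time when 8 h was set against 0 h. Its change per hour was 0.414 higher in KO than in control (SE 0.0700, adjusted p = 0.0038 by limma over 6952 genes), with 4.25% of the 0 h level left at 8 h in control and 45.9% in KO. With straight lines over 0, 4 and 8 h the difference was again 0.414, with an SE of 0.121 and an adjusted p of 0.951. No explanation was tested for it. In KO at 8 h Hist1h4i was 233 ± 18.1, against 5.74 ± 8.11 for Hist1h4f, 3.81 ± 1.82 for Hist2h4 and 2.53 ± 0.0219 for Hist4h4. These levels argue against reads shared from these copies as the source of its KO value at 8 h. Other near-identical histone copies were not looked at, so reads shared with them stay open.

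Fibroblast markers, higher in KO at 0 h, had a median slope difference of −0.064 per hour, which camera set apart from other genes (adjusted p = 0.0033), but not with an estimated correlation (adjusted p = 0.911) or with no filter (0 lists called), while 0 of 23 members were called and fry, which tests the list on its own, gave p = 0.256 (mixed p = 0.221). The scaling of the libraries as the whole cause is argued against, since the median at 0 h after TMM scaling was 0.828. A larger share of fibroblasts in the KO cultures may account for the 0 h difference. It predicts a difference that persists, and the median after TMM was 0.63 at 4 h and 0.086 at 8 h, or 0.182 at 8 h without KO replicate 2 (quartiles 0.104 and 0.417, 21 of 23 markers above 0), between the bounds of 0.3 and 0.1 set for the test, so this explanation and a change of these genes in the stem cells cannot be told apart. The most abundant marker named, Col1a1, was 4094 ± 1456 in control and 8236 ± 1666 in KO at 0 h (log2 change 1.04, adjusted p = 0.0835), 1 of the 23 markers is in another list, and the labels name no feeder cells or sort.

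Genes of chromosomes 6, 8 and 18 shifted together between KO and control after TMM scaling at each time. For chromosome 18, a few strongly changed genes as the cause are argued against, since 69.3% of its 202 genes lay below 0 at 0 h after TMM. Its median at 0 h was −0.375 over the 187 genes left without any gene called after TMM. That value decides little, because a median hardly moves when a few genes are left out. Chromosomes 6 and 8 were not tested in this way. A different copy number of these chromosomes in the cell lines is a candidate explanation that predicts a shift along the whole chromosome. Of 36 medians over consecutive parts of these chromosomes, 36 had the sign of their chromosome. The chromosomes were picked by their shift in the same values, and the times share the cell lines, so these medians are not independent. They show only that the shift was not confined to a part of each chromosome. No other chromosome was divided into parts in this way. A regional change of expression caused by the loss of Zcchc8 was not tested, because genotype and cell line go together. No DNA was measured in the libraries used here.

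Some genes that overlap an abundant gene on the opposite strand held high values. In control at 0 h, for example, Snx22 had 5152 ± 3317 and its partner Ppib 162 ± 49.0, a pair chosen after its values were seen. Reads counted on the strand opposite to the annotation could account for part of this, since over 1510 genes the mean value had a Spearman rho of 0.133 with the length of the exon overlap, above the bound of 0.1 by little. Counting without strand stays open as well: the gene opposite a ribosomal protein gene exceeded it in 2 of 11 pairs (18.2%), between the bounds of 10% and 25%. No biological explanation was tested.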

How the results depend on the processing

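Testing each transcript on its own, leaving out both libraries that stood apart (control 0 h replicate 2 and KO 8 h replicate 2) and leaving out chromosomes 6, 8 and 18 were chosen only after the data were seen. Which control 0 h library is the unusual one is not settled. In its total without Rn45s, replicate 2 (1283659) lay near the KO 0 h libraries (1251479 and 1241274), and replicate 1 (690451) lay lower. Counts without control 0 h replicate 2 therefore rest on the control library with the lower total. Of 51 called results for named genes, 34 were called under every alternative run, and of 1179 values under alternatives 1131 kept the call, 48 lost it and 0 changed direction. Most of these genes were named for the largest called changes, between genotypes with no overlap of replicates. Many alternatives also leave out a library that does not enter the estimate. Kept calls and directions were thus in part fixed by the choice of genes, and the counts over all genes moved more. Rescaling to ERCC spike-ins was not run, since 0 spike-in rows were in the table used. Where 1 library was left out, the lone replicate of its group was assumed to vary like the other groups. Depth limits the calls of low genes, and fewer genes are tested at a mean of at least 50 (2810 against 6952). DESeq2 used its own size factors, so its shifts combine a change of scaling with a change of test. For the other shifts the cause was not tested.

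The counts of genes that moved by more than 1.5 times were as follows, with main values first. At 0 h the higher count of 294 became 121 at a mean of at least 50, 94 with TMM, 70 with the 4 compared libraries alone, 157 with edgeR, 103 with DESeq2 and 1707 without both libraries that stood apart, and leaving out 1 library gave 53 to 1132. The lower count of 5 became 10 with a pseudocount of 4, 20 with no filter, 0 at a mean of at least 50, 27 with TMM, 1 with the 4 libraries alone, 2 with edgeR, 42 with DESeq2, 9 without both libraries and 3 without the chromosomes, and leaving out 1 library gave 1 to 24.

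At 4 h the higher count of 52 became 13 with no filter, 278 with the 4 libraries alone, 97 with DESeq2 and 340 without both libraries (12 to 187 without 1 library). The lower count of 0 became 2 at a mean of at least 50, 17 with TMM, 16 with the 4 libraries alone, 2 with edgeR, 49 with DESeq2 and 26 without both libraries (0 to 8 without 1 library). At 8 h the higher count of 339 became 94 with no filter, 100 with TMM, 582 with edgeR and 152 with DESeq2 (46 to 1011 without 1 library). The lower count of 1 became 0 with a pseudocount of 4, with no filter, at a mean of at least 50 and without the chromosomes, 19 with TMM, 24 with DESeq2 and 2 without both libraries (0 to 33 without 1 library).

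For the control slope the higher count of 31 became 12 with a pseudocount of 4, 3 at a mean of at least 50, 572 with TMM, 7 with edgeR and 498 with DESeq2 (13 to 52 without 1 library). The lower count of 3620 became 1869 at a mean of at least 50, 614 with TMM, 817 for 4 h against 0 h, 744 with DESeq2 and 2309 without both libraries (1849 to 4480 without 1 library). For the KO slope the higher count of 2 became 35 with no filter, 0 at a mean of at least 50, 196 with TMM, 4 for 8 h against 0 h, 270 with DESeq2 and 5 without both libraries (1 to 7 without 1 library). The lower count of 2596 became 1215 at a mean of at least 50, 263 with TMM, 998 for 4 h against 0 h and 366 with DESeq2 (963 to 3141 without 1 library). For the slope difference the higher count of 0 became 1 for 8 h or 4 h against 0 h and 4 with DESeq2 (0 to 5 without 1 library), and the lower count of 0 became 1 without both libraries (0 to 1 without 1 library).

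Lists called by camera at 0 h numbered 2, and 1 at a mean of at least 50, 4 with TMM and 0 with an estimated correlation (2 to 4 without 1 library). For the control slope they numbered 7, and 0 with an estimated correlation (4 to 7 without 1 library). For the slope difference they numbered 1, and 0 with no filter or an estimated correlation, 2 for 4 h against 0 h and 2 without both libraries (1 to 3 without 1 library).

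The replicate numbers gave no clear pairing of the samples. Over the 15 pairs of groups the correlation of same-numbered deviations ran from −0.271 to 0.311, with 4 above 0.1. Within genotype it was −0.115, 0.004 and 0.073 in control and 0.065, 0.176 and 0.232 in KO. A weak pairing within KO is therefore not excluded. With the number as a replicate block, 477 genes were called higher and 12 lower at 0 h, 107 and 6 at 4 h, and 754 and 2 at 8 h. No slope or list count moved by more than 1.5 times. With the number as a block within genotype, run for slopes, 3916 genes were called lower in control and 3023 in KO. Camera then called 5 lists for the control slope.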

Other observations

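The list tests at 4 h and 8 h and the tests of opposite-strand accumulation were chosen only after the data were seen.

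After 8 h in Actinomycin D, several genes not yet named were higher in KO. Kcnq1ot1, an imprinted long noncoding RNA that silences its neighbours and is also in the list of nuclear long noncoding RNAs, was 34.8 ± 6.39 in control and 181 ± 13.2 in KO (n = 2 each; log2 change 2.35, SE 0.407, adjusted p = 0.000166 by limma), and Copg2, which overlaps the imprinted gene Mest, was 372 ± 0.413 and 1945 ± 1030 (2.27, adjusted p = 0.000156). They were the 2 called among 15 imprinted genes, with 3 higher adjusted over the list alone (2 after TMM), and both were called after TMM (adjusted p = 0.00222 for each). Each overlaps a coding gene on the other strand. Of 8 Integrator subunits, Ints5 (2.25, adjusted p = 0.00658), Ints6 (2.15, adjusted p = 0.0116) and Ints2 (1.86, adjusted p = 0.0195) were called higher, and 4 adjusted over the list alone. After TMM scaling 0 were called over all genes and 3 adjusted over the list alone, and the list had a camera adjusted p of 0.145 (adjusted p = 0.989 with an estimated correlation). Of 12 zinc finger and retrovirus silencing genes, Cbx3, a heterochromatin protein, was 27.8 ± 0.387 and 102 ± 14.4 (1.83, adjusted p = 0.00387; 0.026 after TMM), and Suv39h1, a histone methyltransferase, had a change of 2.65 (adjusted p = 0.0179; 0.107 after TMM). Whether these differences grew with time was tested by the slope difference, which was not called for any of these 7 genes (adjusted p = 0.951 for each).

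Of 8 snoRNA and scaRNA genes at 8 h none was called by limma on the deposited scale and 2 were called lower after TMM (0 and 5 adjusted over the list alone), with a median change of −1.28 (−1.95 after TMM) and a camera adjusted p of 1.05e-10 (adjusted p = 0.242 with an estimated correlation). At 4 h the list had no such drop, with a median of 0.45 (0.17 after TMM), 0 of 8 members called and a camera adjusted p of 0.918, where camera's direction was lower though the median lay above 0. Chromosome 17 held 16 of 100 genes called higher at 8 h after TMM (Fisher's exact test over genes, p = 5.44e-05) and 10 of 46 at 4 h (p = 0.000103), while the median change over its 364 genes was −0.017 and −0.023.

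Genes with a coding exon on the opposite strand made up 11.9% of the genes called higher in KO at 0 h and 17.3% of those at 4 h, against 23.9% of tested genes, and at 4 h Fisher's exact test gave p = 0.328 (0.222 after TMM). At 8 h the share was higher than among tested genes, at 32.7% (Fisher's exact test p = 0.000103), and 20% after TMM (p = 0.409). A hypothesis, prompted by the 0 h calls, is that reads from the strand opposite to the annotation accumulate at the genes called at 0 or 4 h in KO. The KO 8 h replicates appear to differ in the share of reads on each strand, judged from genes with and without an overlap, whose median log2 replicate 2 over replicate 1 after TMM was 0.418 and −0.123, against −0.305 for ribosomal protein genes. For 114 called genes without fibroblast markers this median was 0.25 (quartiles −0.222 and 0.898), and 0.257 for the 101 without an overlap, above the bound of 0.2 set for the test. The values needed are therefore present, but the quartiles are wide, the 2 libraries differ in other ways too, and the strand of the reads was not seen.

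For the slope difference, 100 splits of genotype within each time were drawn from 108 possible ones. The real split called 0 genes and the highest of the others 704. With a real count of 0, all 100 of the 100 splits call as many by construction, so this count decides nothing. At an unadjusted p below 0.05 the real split had 350 genes, 35 of the 100 splits had as many, the real one included, and the highest other had 2079, so chance is not excluded for the unadjusted count. Exchanging genotype at 1 time turns a constant difference between genotypes into a slope difference, so the calls of other splits do not show a structure other than genotype.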
